A study of Rattus norvegicus with 8 samples.

How the data were processed

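Hippocampal RNA of 8 male rats, 4 given vehicle and 4 given Y+I, was labelled with Cy3 and hybridised to 1-colour Agilent rat gene expression arrays, per the labels' protocols. Groups and animal numbers were taken from the sample titles. Per the file headers, the images were read with Agilent Feature Extraction 10.5.1.1, which gave for every spot a mean and a local background intensity and a processed intensity that is background-subtracted, detrended and not normalised between arrays. The deposited value table holds log2 values of the same arrays whose scale is not given in the sources used here. Set against the scanner values, its columns had a slope of 0.997 and r of at least 0.998, with the 75th percentile close to 0.01 and medians between -3.51 and -3.35. Its scale and centring were therefore taken as log2 signal minus a 75th percentile. By the median of each array, it lay 0.59 to 0.67 log2 units above scanner values centred as the main values below. Its centring thus differed from theirs, and it served only as an alternative.

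The main values were log2 of the processed signal minus the 75th percentile of the array over noncontrol spots. Spots marked as non-uniform or as population outliers were set to missing, and spots of a probe were averaged. No spot was saturated. Of 30367 probes, 21370 were kept because they were well above background on all 4 arrays of a group, on at least 50% of the probe's spots, and had at least 3 values per group. A dim probe has only an uncertain fold change, and the processed signal near background is a surrogate value, which can change the size of a low gene's difference. Symbols were updated through the RefSeq table of rat assembly GRCr8: 18004 probes matched by accession, 2320 by symbol and 626 by a unique synonym, 1999 kept the name in the file and 7418 had none. Each symbol was represented by its brightest kept probe and each unnamed probe by itself, which gave 18803 features. Of 65 changed genes with several kept probes, 4 had a probe of the other sign. Probe positions are those in the files, on rat build rn4; the sources used here do not say which part of a transcript a probe covers.

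Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 26 gene lists were tested with camera at an inter-gene correlation of 0.01 and adjusted over the lists, and again with the correlation estimated for each list, where 0 of the 26 passed. Without adjustment, 8 lists had a camera p under 0.05 at the preset correlation and 5 with the estimated correlation. The rotation test fry, which asks only whether the genes of a list move and not whether they move more than others, called 5 lists in one direction and 19 in either direction. Set tests used the 18795 features without a missing value. The 26 lists, the rule for named genes and the alternatives, except cyclic loess and the omission of Y+I animals 2 and 3, were fixed before the data were examined. The rule took the 12 largest changes in each direction at an adjusted p under 0.05, the 2 to 4 members of each list with the smallest p, and always Bdnf, Vegfa, Adra2a, Adra2c, Fos and Arc, with provisional names left out. A result that this rule names is not reported here. Replicates are separate animals per the labels.

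The procedure was tested on simulated data with the means and spreads of the real features. Of 200 features changed in that simulation among 18803, 31.3% of those at 1.5-fold, 58.2% at 2-fold and 89.4% at 4-fold were recovered with the right sign, and 17 of the 136 calls (12.5%) were false, more than the threshold of 0.05 would give. The list test made 0 false calls with camera over 20 simulated draws of 26 lists and recovered the glucocorticoid list, shifted by 0.5, in 20 of 20; genes were simulated independently, so correlation within lists was not tested there. Alternatives covered quantile, median and cyclic loess normalisation, normexp background correction with an offset of 50, the value table, other filters and probe summaries, a block for the animal number, variance models, array weights, other thresholds, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.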

Results

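The series measured messenger RNA in the hippocampus of male Sprague Dawley rats aged 3 months, after 7 days of vehicle or of a combination of yohimbine and imipramine (Y+I), with tissue taken 2 h after treatment. Yohimbine blocks alpha2-adrenoceptors, and imipramine is a tricyclic antidepressant that inhibits the reuptake of noradrenaline and serotonin. Each group held 4 animals, and each animal was hybridised to its own 1-colour array, so n = 4 for every group mean. Arrays with either drug alone were not analysed here, and the comparison therefore answers how the hippocampal transcriptome differed under the combination, without separating the drugs. Of the 58717 noncontrol spots per array, 76.4%, 76.7%, 78.1% and 79.7% were well above background in vehicle animals 1 to 4, against 70.9%, 65.3%, 64.4% and 74.8% in Y+I animals 1 to 4. The 75th percentile of the processed signal lay between 1939 and 2106 scanner units in vehicle and between 1045 and 1971 in Y+I. Negative control spots had an SD of 2.16 to 3.09 units in vehicle and 2.04 to 6.86 in Y+I. The median SD of a gene between animals was 0.134 log2 units in vehicle and 0.239 in Y+I, and the number of arrays limits the precision of every value. All 8 arrays shared a slide and a scan, with vehicle on one row of the slide and Y+I on the other, so slide row and treatment cannot be told apart.

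**Figure D1:**
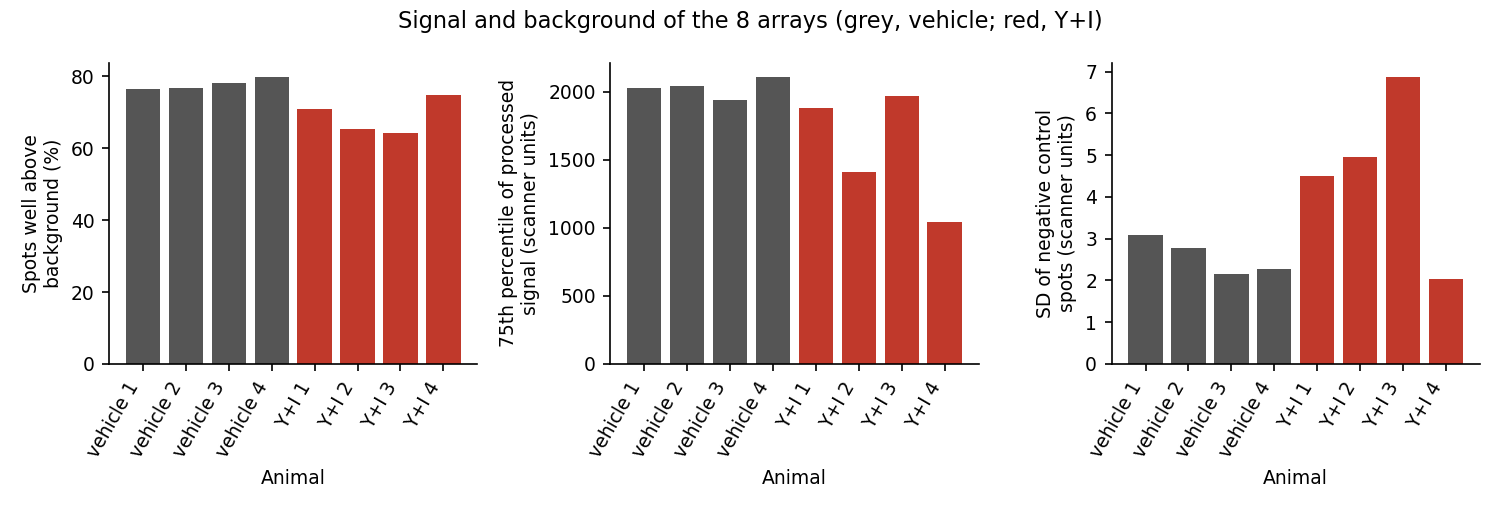
Signal and background of each array, with bars for the 4 vehicle animals in grey and the 4 Y+I animals in red: the percentage of spots well above background, the 75th percentile of the processed signal and the SD of the negative control spots, the last 2 in scanner units. The Y+I arrays had 64.4% to 74.8% of spots well above background, below the 76.4% to 79.7% of the vehicle arrays.

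Y+I animals had more messenger RNA for the histamine-synthesising enzyme Hdc, the ceramidase Acer2 and the kinase Sgk1, and less for the neuropeptide Grp, the neurexin ligand Nxph3 and the nicotinic receptor subunit Chrna4. Of 18803 features tested, 439 changed at an adjusted p under 0.05 in limma, 139 of them higher in Y+I and 300 lower (31.7% higher). Changes of at least 2-fold were seen for 35 of the higher and 126 of the lower features. In all 439 the values of the 4 Y+I animals did not overlap those of the 4 vehicle animals, as was so for 11.7% of all features, where chance gives 2.86%. With no adjustment, 2938 features had p under 0.05, 1215 higher and 1723 lower. Of the 300 lower features, 180 were well above background on all 4 Y+I arrays, 120 were not on every one, and 60 were so on none. The filter kept probes well above background on all 4 arrays of either group, so these 120 entered through vehicle, where they were higher. Of the higher features, 1 was not well above background on every vehicle array. The filter therefore shapes part of the split between higher and lower. After normexp background correction the split turned to 401 higher and 203 lower (66.4% higher), without a filter on background to 3361 and 526 (86.5% higher), and with a filter that asked for all 8 arrays to 161 and 211 (43.3% higher). Under normexp the median of all features moved from -0.02 to 0.09. The fit without a filter tested 26725 features, adding dim ones whose processed signal near background is a surrogate. The lowest signal well above background lay between -8.97 and -7.42 in Y+I arrays and between -9.66 and -8.28 in vehicle arrays. Rises among such dim features may reflect that level, so the unfiltered split does not measure the balance of changes. Without vehicle animal 1, 2, 3 or 4 the count was 201, 189, 193 or 121, and without Y+I animal 1, 2 or 4 it was 261, 285 or 278 (18.4% higher without the last). Without Y+I animals 2 and 3, the pair of arrays with the fewest spots well above background, 164 features passed, 59 higher and the rest lower.

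The 12 named genes that rose most were Hdc, Acer2, Prss23, Ccdc27, Tpsab1, Sgk1, Exoc3l4, Tacr2, Ch25h, Apold1, Rpe65 and Epha8. Hdc rose 5.54-fold, from a normalised log2 signal of -4.36 ± 0.44 (SD, n = 4) in vehicle to -1.89 ± 0.40 in Y+I (limma adjusted p = 0.00568). Its probe lies at 114119325 to 114119384 on chromosome 3 of the rat build rn4. Tpsab1, a mast cell tryptase, rose 3.05-fold (adjusted p = 0.00829) from a dim signal of -6.74 ± 0.17 to -5.13 ± 0.42. Acer2, an alkaline ceramidase (chromosome 5, 106233740 to 106233799), rose 4.66-fold from -1.97 ± 0.44 to 0.25 ± 0.63 (adjusted p = 0.0136). The serine protease Prss23 and the coiled-coil gene Ccdc27 rose 3.68-fold and 3.63-fold. Sgk1, a kinase induced by serum and glucocorticoids (chromosome 1, 23501718 to 23501777), rose from -0.78 ± 0.22 to 0.77 ± 0.48, by 2.92-fold (adjusted p = 0.0143). Log2 fold changes were 1.51 ± 0.26 (SE) for Exoc3l4, 1.48 ± 0.29 for the tachykinin receptor Tacr2, 1.44 ± 0.24 for the cholesterol hydroxylase Ch25h, 1.40 ± 0.23 for the endothelial early response gene Apold1, 1.34 ± 0.22 for the retinoid isomerase Rpe65 and 1.29 ± 0.17 for the ephrin receptor Epha8. Hdc, Acer2, Prss23, Ccdc27, Tpsab1, Sgk1 and Epha8 passed the threshold whichever array was left out, although normexp lowered Tpsab1 to 0.82 and Epha8 to 0.64, and Tpsab1 lost its call without Y+I animals 2 and 3 (adjusted p = 0.0524). Exoc3l4 passed in 3 of the 8 such fits, Ch25h, Apold1 and Rpe65 in 2 each, and Tacr2 in 1. Their highest adjusted p was 0.0711 (Exoc3l4), 0.0672 (Ch25h), 0.0776 (Rpe65) and 0.0974 (Tacr2), each without vehicle animal 4, and 0.0642 (Apold1) without vehicle animal 1.

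The genes that fell most were Cyp11b1, Plagl1, Grp, Nxph3, Chrna4, Kcnf1, Nhsl3, Rprm, Slc6a5, Npsr1, Myh3 and Calca. Grp, which encodes gastrin-releasing peptide (chromosome 18, 62176219 to 62176278), fell 7.87-fold, from 1.92 ± 0.30 (SD, n = 4) in vehicle to -1.05 ± 0.37 in Y+I (limma adjusted p = 0.00139). The neurexophilin gene Nxph3 (chromosome 10, 84201916 to 84201975) fell 7.05-fold, from 2.90 ± 0.24 to 0.08 ± 0.58 (adjusted p = 0.0047). The skeletal myosin heavy chain gene Myh3 fell 5.91-fold (adjusted p = 0.00139) and Calca, which encodes calcitonin and calcitonin gene-related peptide, 5.50-fold (adjusted p = 0.0132). Chrna4 was well above background on 3 of the 4 Y+I arrays and fell 6.76-fold. The potassium channel subunit Kcnf1, Nhsl3 and the glycine transporter Slc6a5 were well above background on 2 Y+I arrays each, with log2 fold changes of -2.70 ± 0.29 (SE), -2.68 ± 0.49 and -2.59 ± 0.41. With normexp these values shrank to -1.02, -1.01 and -0.90, and those of Chrna4, Calca and Myh3 to -1.39, -1.61 and -1.95, all still past the threshold. A second probe gave -0.59 for Nhsl3 and -0.31 for Slc6a5, and both lost their calls with the mean of probes (adjusted p = 0.0579 and 0.0651). The steroid hydroxylase Cyp11b1, the imprinted zinc finger gene Plagl1, the cell cycle gene Rprm and the neuropeptide S receptor gene Npsr1 were not well above background on any Y+I array. On the main scale their signal was 11.7-fold, 9.76-fold, 6.35-fold and 5.91-fold lower in Y+I (adjusted p = 0.012, 0.0156, 0.00706 and 0.00635). The value for Npsr1 rests on the brighter of its 2 probes, and the other gave a log2 fold change of -0.10. Each such value sets the vehicle mean against the higher, per array, of the gene's own signal and the lowest signal well above background. It is not a lower bound on the true fall, because the processed signal near background is a surrogate. With normexp background correction these 4 genes lost their calls, with log2 fold changes of -0.83, -0.67, -0.51 and -0.26, and so did all but 8 of the 120 lower features that were not well above background on every Y+I array. Of the 180 others, all 180 stayed below 0 under that correction and 138 still passed. Leaving out arrays in turn ended the call of Plagl1 without vehicle animal 1 (adjusted p = 0.0502), of Slc6a5 without vehicle animal 4 (0.0614) or Y+I animal 2, and of Nhsl3 in 5 of the 8 fits (up to 0.0967 without vehicle animal 4).

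**Figure D2:**
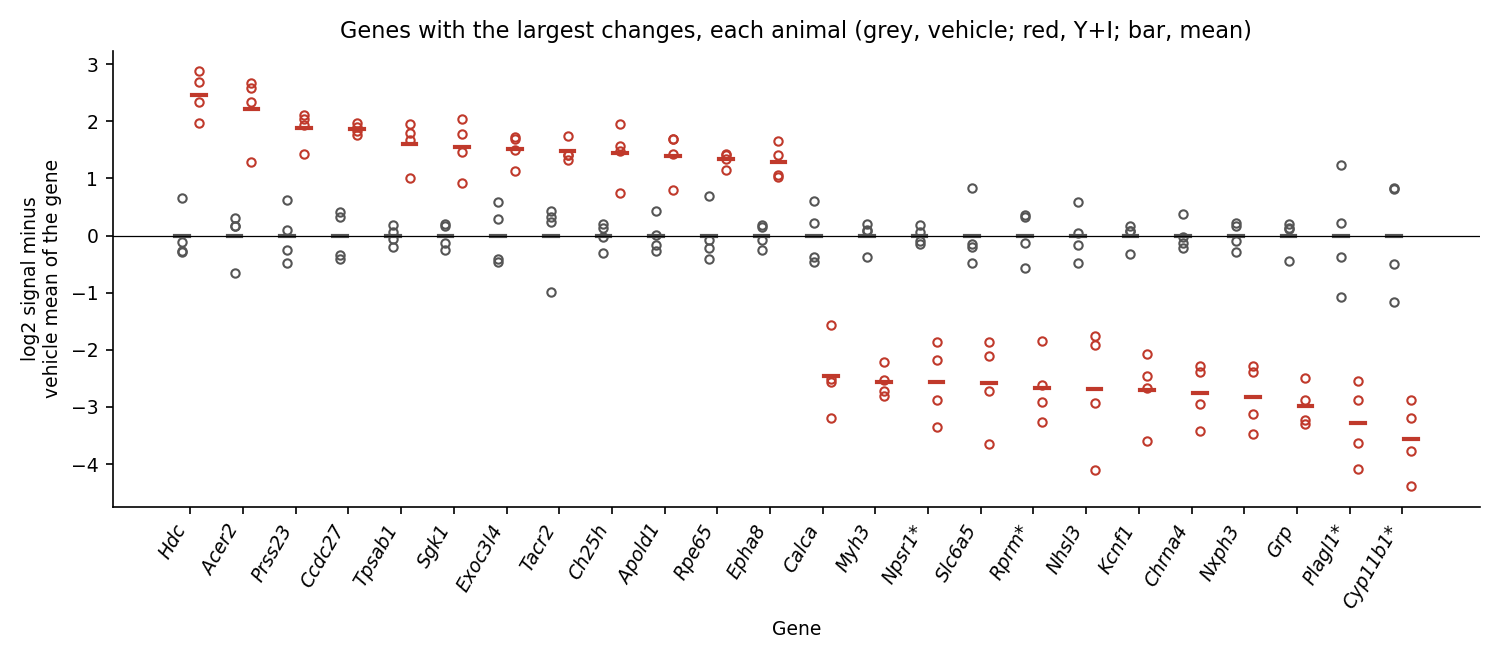
Normalised log2 signal of each animal minus the vehicle mean of the gene, for the 12 genes that rose most and the 12 that fell most, with vehicle in grey, Y+I in red and bars at the group means. The groups did not overlap for any of the 24 genes, and an asterisk marks genes not well above background on any Y+I array.

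Glucocorticoid-responsive genes were shifted upward as a list in Y+I, with a median log2 fold change of 0.59 over 23 measured members, 20 of them above 0. The list passed in camera at an adjusted p of 3.92e-10 over 26 lists, against an adjusted p = 0.197 with an estimated correlation. Of the 23 members, 7 rose and 16 did not pass over all genes tested, and 15 were higher and 1 lower when adjusted over the list alone. Beside Sgk1, the mineralocorticoid receptor gene Nr3c2 rose by 0.62 ± 0.11 log2 units (SE, adjusted p = 0.0246), the glucocorticoid receptor co-chaperone gene Fkbp5 by 0.57 ± 0.10 (adjusted p = 0.0298) and the transcription factor gene Klf9 by 0.55 ± 0.11 (adjusted p = 0.0351). Fkbp5 went from 0.75 ± 0.07 (SD, n = 4) in vehicle to 1.32 ± 0.15 in Y+I, with a probe on chromosome 20 at 6637600 to 6637659. The list passed whichever array was left out, with medians of 0.53 to 0.67. Among its members, Nr3c2 lost its call without any 1 of the vehicle animals (adjusted p up to 0.0909 without animal 4), Fkbp5 in 7 of the 8 fits (up to 0.105 without vehicle animal 4) and Klf9 in all 8 (up to 0.103 without vehicle animal 2).

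**Figure D3:**
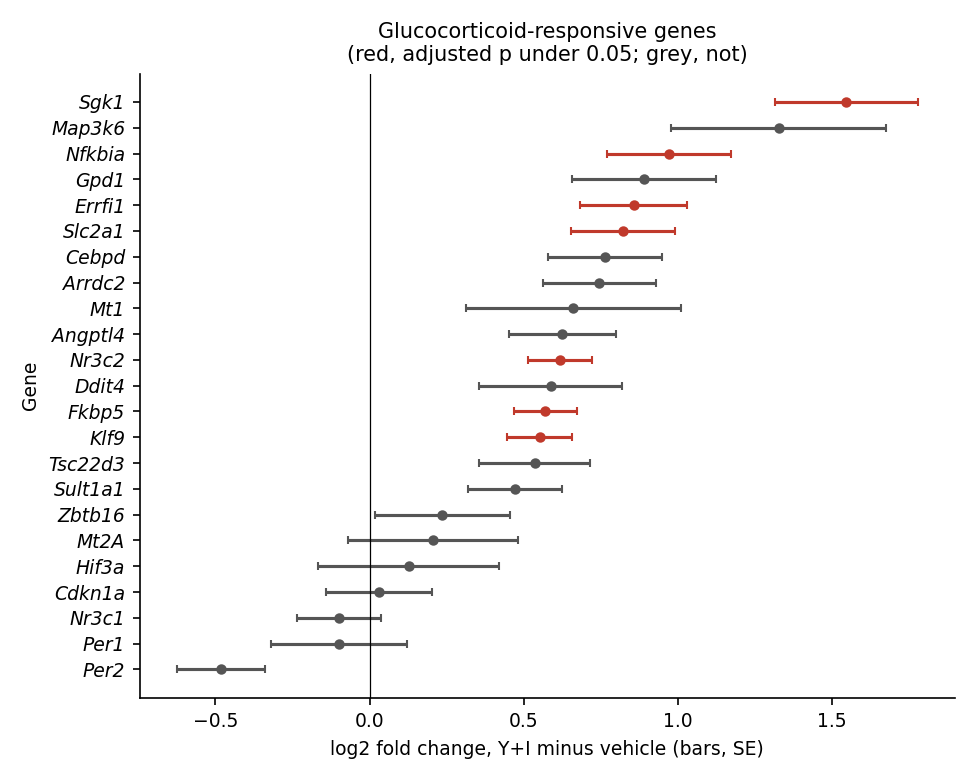
Log2 fold change, Y+I minus vehicle, with its standard error, for the 23 measured members of the glucocorticoid-responsive list; red marks an adjusted p under 0.05 over all genes. Of the 23 members, 20 lie above 0, from 0.03 for Cdkn1a up to 1.55 for Sgk1, with a median of 0.59 over the list, and Per2 lies lowest at -0.48.

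Receptors, transporters and enzymes of the monoamine systems fell as a list, with a median log2 fold change of -0.26 over 25 measured members (camera adjusted p = 0.0119, and adjusted p = 0.197 with an estimated correlation). Its members Drd1 and Drd2 also belong to the list of thalamus, habenula and striatum markers, which fell as well. No member rose, 4 fell and 21 did not pass; adjusted over the list alone, 7 were lower and 1 higher. The serotonin receptor gene Htr2c (chromosome X, 31013361 to 31013420) fell 3.96-fold, from 0.16 ± 0.54 (SD, n = 4) to -1.83 ± 0.28 (adjusted p = 0.0095), and Htr3a fell 1.98-fold (adjusted p = 0.0095). The adrenoceptor gene Adra1b fell by 0.91 ± 0.16 log2 units (adjusted p = 0.0275) and the dopamine receptor gene Drd2 by 0.60 ± 0.11 (adjusted p = 0.0278). Among the targets of yohimbine, Adra2a was not well above background on any Y+I array and did not pass (2.41-fold lower on the main scale, adjusted p = 0.0934), and its log2 fold change of -1.27 became 0.00 with normexp. Adra2c had a log2 fold change of -0.26 ± 0.18 (adjusted p = 0.545). With normexp the list did not pass and its median turned to 0.05 (camera adjusted p = 0.254). The median of all features was then 0.09, and the test direction of the list stayed down. Without Y+I animal 2 the list did not pass either (adjusted p = 0.0622, median -0.17). With the filter on all 8 arrays the list passed (camera adjusted p = 0.0234), but its median shrank to -0.11. Htr2c and Htr3a passed in all 8 leave-one-out fits but not without Y+I animals 2 and 3 together (adjusted p = 0.0668 and 0.0578), nor did Htr3a with a block for animal number (0.0592). Adra1b passed in 3 (up to 0.0967 without vehicle animal 4) and Drd2 in 2 (up to 0.0843 without vehicle animal 4).

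Markers of neighbouring tissue also shifted. The list of thalamus, habenula and striatum markers fell, with a median log2 fold change of -0.55 over 18 measured members (camera adjusted p = 0.00139, and adjusted p = 0.197 with an estimated correlation). Its 20 listed genes include 8 that other lists also hold. Slc17a6, the vesicular glutamate transporter gene abundant in thalamus, fell 2.25-fold (adjusted p = 0.0291), Drd2 fell, and the tachykinin gene Tac3 rose by 0.81 ± 0.14 log2 units (adjusted p = 0.0255). The calcium-binding protein gene Calb2 had a log2 fold change of -0.83 ± 0.18 (adjusted p = 0.0571). Meningeal and fibroblast markers fell, with a median of -0.42 over 16 members (camera adjusted p = 0.000105, and adjusted p = 0.197 with an estimated correlation). Of these, the transporter gene Slc6a13 fell 2.03-fold (adjusted p = 0.0106), the collagen gene Col1a1 2.04-fold (adjusted p = 0.0135, with a log2 fold change of -0.16 at its other probe) and Igfbp2, which encodes a binding protein of insulin-like growth factors, 1.66-fold (adjusted p = 0.0383). The other 13 members did not pass, and 5 were lower when adjusted over the list alone. Both lists passed whichever array was left out and under normexp, where their medians shrank to -0.12 and -0.15. Slc6a13 and Col1a1 did so too, although Slc6a13 did not pass without Y+I animals 2 and 3 (adjusted p = 0.0641), whereas Slc17a6 passed in 2 of the 8 fits (up to 0.0967 without vehicle animal 4), Tac3 in 4 (up to 0.0926 without vehicle animal 4) and Igfbp2 in 1 (up to 0.11 without vehicle animal 2).

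Endothelial and mural markers fell as a list (median -0.19 over 19 members, camera adjusted p = 0.0285, and adjusted p = 0.219 with an estimated correlation), although no single member passed. Oligodendrocyte markers rose as a list (median 0.12 over 20 members, camera adjusted p = 0.0421, and adjusted p = 0.503 with an estimated correlation), with 1 member, the aspartoacylase gene Aspa, higher by 0.72 ± 0.13 log2 units (adjusted p = 0.0289). The endothelial list lost its call without vehicle animal 2 (adjusted p = 0.0506), Y+I animal 2 (0.0831) or Y+I animals 2 and 3 (0.103), with normexp (0.0886) and with cyclic loess (0.0721). The oligodendrocyte list lost its call without vehicle animal 3 (adjusted p = 0.351) or Y+I animal 1 (0.0508), 2 (0.0622), 3 (0.309) or 2 and 3 together (0.486), with normexp (0.454), quantile (0.0968) or cyclic loess normalisation (0.0721), with the filter on all 8 arrays (0.1) and in fry (0.237). Aspa itself passed in 3 of the 8 fits (up to 0.0996 without vehicle animal 4). Astrocyte markers (median -0.04 over 19 members, adjusted p = 0.635), microglia and inflammation markers (-0.07 over 28, adjusted p = 0.418) and choroid plexus markers (-0.24 over 9, adjusted p = 0.418) did not pass, and none of their members did, but astrocyte markers passed as lower with normexp (adjusted p = 0.0378). The choroid plexus median shrank to -0.06 with the filter on all 8 arrays. Blood cell markers did not pass as a list (median -0.23, or 0.16 with normexp, but mean 0.18 over 8, adjusted p = 0.418), except with the filter on all 8 arrays (median -0.86, adjusted p = 0.00344). The haemoglobin gene Hbb and the haem synthesis gene Alas2 fell 1.99-fold (adjusted p = 0.017) and 1.87-fold (adjusted p = 0.0289), whereas the neutrophil gene S100a9 had a log2 fold change of 2.08 ± 0.60 (adjusted p = 0.129). Hbb passed in 5 of the 8 leave-one-out fits (up to 0.0633 without vehicle animal 4) and Alas2 in 1 (up to 0.0844 without vehicle animal 2).

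**Figure D4:**
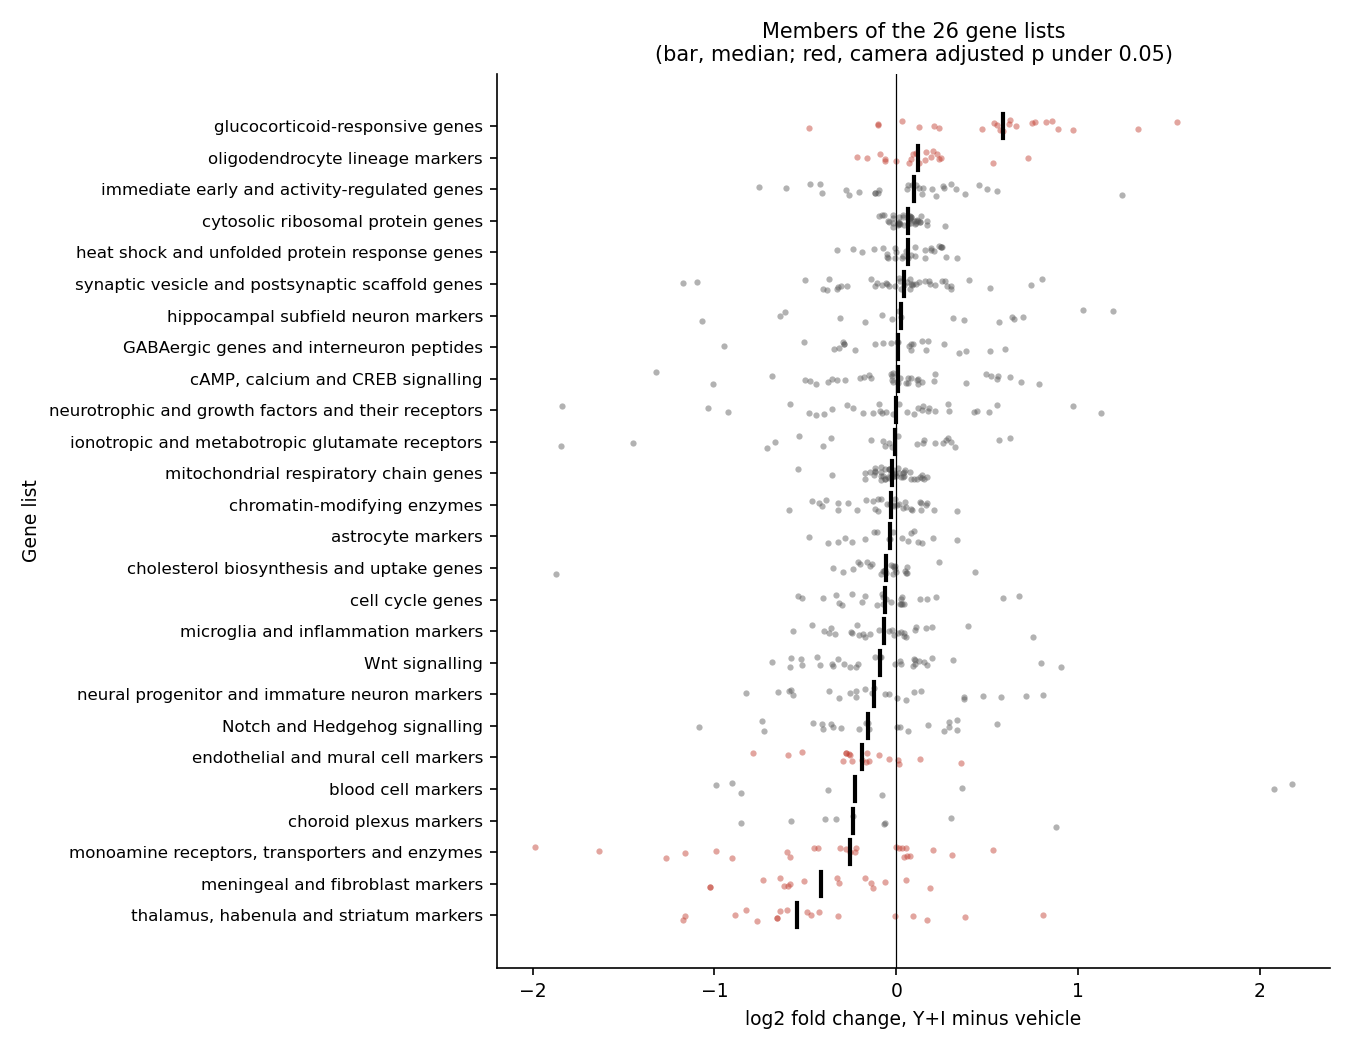
Log2 fold change, Y+I minus vehicle, of every measured member of the 26 gene lists, with black bars at the list medians and red for the 6 lists that passed in camera. Medians run from -0.55 for thalamus, habenula and striatum markers to 0.59 for glucocorticoid-responsive genes, the list farthest above 0.

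Immediate early and activity-regulated genes did not pass as a list (median 0.10 over 30 members, camera adjusted p = 0.24). The phosphatase gene Dusp5 rose 2.36-fold (adjusted p = 0.0106, under 0.05 whichever array was left out but 0.0641 without Y+I animals 2 and 3), while Fos and Arc had log2 fold changes of -0.61 ± 0.27 (adjusted p = 0.325) and -0.10 ± 0.20 (adjusted p = 0.858). Jun was at -0.75 ± 0.17 (adjusted p = 0.0584). Neurotrophic and growth factors and their receptors did not pass either (median -0.00018 over 34 members, adjusted p = 0.76), and Bdnf and Vegfa stood at 0.06 ± 0.11 (adjusted p = 0.852) and 0.12 ± 0.14 (adjusted p = 0.742). Within that list the vascular growth factor receptor gene Kdr fell 2.05-fold (adjusted p = 0.00932, and under 0.05 whichever array was left out) and the growth factor gene Fgf2 rose by 0.51 ± 0.10 log2 units (adjusted p = 0.0407). The neurotrophin receptor gene Ngfr, not well above background on any Y+I array, was 3.58-fold lower on the main scale (adjusted p = 0.0155), a call lost with normexp. Ngfr passed in 5 of the 8 leave-one-out fits (up to 0.0614 without vehicle animal 4) and Fgf2 in 1 (up to 0.121 without vehicle animal 2).

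Neuronal lists held single changed genes without a shift of the whole. Among glutamate receptors (median -0.0073 over 24 members, camera adjusted p = 0.76), Grin3a fell by 1.45 ± 0.29 log2 units (adjusted p = 0.0381), Grik1 by 0.67 ± 0.13 (adjusted p = 0.0366) and Grm8, well above background on 2 Y+I arrays, by 1.85 ± 0.31 (adjusted p = 0.0222). Among genes of cAMP, calcium and CREB signalling (median 0.0077 over 39, adjusted p = 0.635), the kinase genes Camkk2 and Camk2a rose by 0.62 ± 0.11 (adjusted p = 0.03) and 0.78 ± 0.15 (adjusted p = 0.0366). The adenylyl cyclase gene Adcy9 rose by 0.69 ± 0.13 (adjusted p = 0.0379), whereas Adcy8 fell by 1.01 ± 0.19 (adjusted p = 0.034). Synaptic vesicle and scaffold genes (median 0.04 over 43, adjusted p = 0.635) included falls of Slc17a6, given above, and of the syntaxin gene Stx1a by 0.50 ± 0.10 (adjusted p = 0.0391), GABAergic genes (median 0.01 over 25, adjusted p = 0.76) had no member that passed, and subfield neuron markers (median 0.03 over 17, adjusted p = 0.186) had no member that passed over all genes, but 4 higher and 2 lower when adjusted over the list alone. Leaving out arrays in turn ended these calls in 4 (Grm8) to 8 (Camk2a) of the 8 fits, with adjusted p up to 0.079 for Grm8, 0.124 for Grin3a, 0.115 for Grik1, 0.107 for Camkk2, 0.087 for Adcy8 and 0.124 for Stx1a without vehicle animal 4, 0.106 for Camk2a without vehicle animal 2 and 0.103 for Adcy9 without vehicle animal 1. Normexp also ended the calls of Grm8 (-0.41, adjusted p = 0.197) and Grin3a (-0.63, adjusted p = 0.0574), and the value table that of Grm8 (adjusted p = 0.146). Median, mean and test differed in sign for the neurotrophic, signalling, glutamate, GABAergic, synaptic and blood cell lists.

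Lists of growth, metabolism and gene regulation did not pass in the main comparison. Neural progenitor and immature neuron markers had a median of -0.12 over 25 members (camera adjusted p = 0.617), with the neuronal RNA-binding protein gene Elavl4 lower by a log2 fold change of -0.65 ± 0.09 (adjusted p = 0.0133, and 0.059 without vehicle animal 4) and Tac3, given above, higher by 0.81 ± 0.14 (adjusted p = 0.0255). Cell cycle genes had a median of -0.06 over 26 (adjusted p = 0.635), chromatin-modifying enzymes -0.03 over 34 (adjusted p = 0.617), Wnt genes -0.09 over 31 (adjusted p = 0.33) and Notch and Hedgehog genes -0.16 over 23 (adjusted p = 0.418). Wnt3 fell by 0.58 ± 0.09 log2 units (adjusted p = 0.0194, and up to 0.0704 without vehicle animal 4), a call also lost with normexp and passed in 5 of the 8 leave-one-out fits. Cholesterol genes had a median of -0.05 over 27 (adjusted p = 0.371), and passed as lower with normexp (0.0101) and without Y+I animals 2 and 3 (0.0181). Heat shock and unfolded protein response genes (0.06 over 29, adjusted p = 0.136), mitochondrial respiratory chain genes (-0.03 over 46, adjusted p = 0.76) and cytosolic ribosomal protein genes (0.06 over 42, adjusted p = 0.104) had no member that passed. With normexp the mitochondrial list passed as lower (adjusted p = 0.00546). The ribosomal list passed without vehicle animal 1 (adjusted p = 0.0484), Y+I animal 1 (0.0333) or Y+I animal 3 (0.00127). Over all arrays its estimated correlation was 0.63, and with it the camera adjusted p was 0.863. Without Y+I animal 2 its median turned to -0.02.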

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

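The tests of activity-induced genes, of slide row, of tissue from neighbouring regions and of the glucocorticoid list under other splits of the arrays were chosen only after the result was seen.

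Of 268 groups of 4 values tested, 8 held a sample far from the other 3, 4 of them in vehicle and 4 in Y+I. This is a smaller share than the 1 in 20 or so that chance gives, so the flags need no cause beyond chance. The gap to the nearest of the others, as a share of the whole range of the group, is given for each. Acer2 in vehicle animal 3 was at -2.62, against -1.80 to -1.67 in the others (0.858). Grp in vehicle animal 2 was at 1.48, against 2.04 to 2.12 (0.881). Tacr2 in vehicle animal 1 was at -4.32, against -3.09 to -2.89 (0.864). The vesicular glutamate transporter gene Slc17a6 in Y+I animal 4 was at -0.17, against -0.96 to -0.85 (0.852). Y+I animal 2 stood apart for the endothelial gene Emcn (-4.77 against -4.06 to -3.95, 0.864), the cytokine gene Il1b (-4.46 against -5.52 to -5.37, 0.861) and the myelin gene Mog (2.98 against 2.49 to 2.56, 0.851). Vehicle animal 3 had 1051 spots marked as non-uniform or as population outliers, against 499 to 592 in the others (0.832).

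Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many changed genes (439, against 3 in the highest other). That is the smallest share that 35 splits can give. The other splits also mix vehicle with Y+I arrays, so chance is not excluded for that count. For the gene lists, 3 of the 35 splits gave as many (6, against 6 in the highest other), so chance cannot be excluded for the number of lists. No slide row held both groups (0 rows), and slide row and treatment cannot be told apart for any result.

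The genes lower in Y+I may in part reflect tissue composition, since they include Slc17a6 and Slc6a13 from the lists of neighbouring and meningeal tissue. Whether the largest falls, such as those of Grp and Nxph3, have this cause was not tested. Markers of ventral hippocampus, subiculum, entorhinal cortex and neocortex gave a camera p of 0.218 (median -0.15 over 20 members, 5 of them above 0). This leaves less ventral and retrohippocampal tissue open, because that list leaves out genes already seen to have changed. The 10 members of the thalamus, habenula and striatum list that no other list holds had a median of -0.48, with 8 below 0, as less tissue of neighbouring regions in Y+I would need, although the fall of the whole list was known when this was tested. Within the list, Tcf7l2 (0.09 ± 0.15, SE) and Adora2a (-0.01 ± 0.11) lay near 0 and Tac3 was higher, which such a loss alone does not explain. An effect of the treatment on these genes stays open and untested.

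The 120 lower genes that were not well above background on every Y+I array (median -1.20) could owe part of their change to higher background and noise on those arrays. Uncalled genes of the same brightness in vehicle had a median of -0.10 (quartiles -0.30 to 0.12), far from that of the 120 genes and past the bound set for excluding this explanation. Called genes were left out of that comparison, which removed the clearest falls and held its median nearer 0, so that bound does not settle it. In addition, with normexp the median of the 120 genes was -0.04, 71 lay below 0 and 8 still passed, values seen before the verdict was drawn. Normexp adds an offset of 50 ahead of scaling, which by its construction raises dim signals and shrinks their differences, more so on dimmer arrays. The 75th percentile of the signal was lowest in Y+I animals 4 and 2 (1045 and 1408), so part of this loss of falls is built in. With quantile normalisation 82 of the 120 genes passed, and with cyclic loess 117. Both start from the same processed signal on which the 120 genes were called, so they cannot test background. Background and treatment therefore cannot be told apart for these 120 genes.

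The rise of glucocorticoid-responsive genes in Y+I is a candidate for follow-up. Brightness or normalisation of the Y+I arrays as its cause is argued against by a lowest median of 0.57 over quantile, cyclic loess, normexp and the fit without Y+I animals 2 and 3, with a highest camera p of 6.79e-08. A general rise of activity-induced genes at the time of sampling is argued against by a median of 0.10 in the immediate early list (quartiles -0.18 to 0.26). Tissue was taken 2 h after treatment, so a rise that had ended by then was not tested. Members moved both ways, with 18 of 30 above 0, Dusp5 at 1.24 and Jun at -0.75. The fry adjusted p for either direction was 1.16e-05. Because this list was the farthest from 0 of the 26, each of the 35 splits was given the same choice of any list. Of these, 1, the real one, put a median as far from 0 (0.588, against 0.518 in the highest other). The margin is narrow, but that other split set vehicle animal 1 with Y+I animals 1, 2 and 4. It therefore kept part of the real grouping, and the margin does not measure chance. The share is the smallest that 35 splits can give, so chance is not excluded. The camera adjusted p with an estimated correlation was 0.197. A response to corticosterone or to the drugs may underlie the rise, but neither hormone levels nor either drug alone were analysed here, and slide row stays open.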

How the results depend on the processing

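Cyclic loess and leaving out Y+I animals 2 and 3 were chosen only after the data were seen. The number of changed genes (439, 139 higher and 300 lower) stayed within 1.5 times with quantile normalisation (388), a median shift (390), the value table (375), a filter on all 8 arrays (372), the mean of probes (417), every probe (431) and marked spots kept (440). Without a filter it was 3887 (3361 higher, 526 lower), with cyclic loess 713 (257, 456), at an adjusted p under 0.10 775 (279, 496), at an unadjusted p under 0.05 with 1.5-fold 1066 (356, 710) and without Y+I animals 2 and 3 164 (59 higher, the rest lower). Normexp gave 401 higher, and both the trend with robust variance and array weights gave 212 higher. Leaving out 1 array gave 121 to 355 genes (34 to 116 higher, 87 to 239 lower), with fewer samples by construction. With a block for animal number it was 144 (34, 110), of which 130 were shared; the pairing check gave correlations of -0.112 to 0.046 between arrays of the same number, which gives no support for pairing by number. Animal number equals slide column on all 8 arrays, so this block is also one for slide column. A block for slide or scan could not be run, since all arrays shared 1 slide and 1 scan. Where not stated, the cause was not tested.

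Of 1175 results for the 54 changed named genes under the alternatives, 924 kept their call, 251 lost it and 0 reversed, and 87 results of other named genes gained one. Without Y+I animals 2 and 3, 33 of the 54 lost their calls, and with the block for animal number 26 did. With an estimated correlation 0 lists passed, and leaving out 1 array gave 3 to 7. Normexp turned the log2 fold changes of these genes, none of which had passed: Abcb1a 0.11, Adra2a 0.000226, Gli1 0.012, Hey2 0.12, Heyl 0.052, Nos1 0.15, Nusap1 0.12, P2ry13 0.24, Sfrp1 0.063 and Sostdc1 0.15. It also turned the median or the test direction of the lists of neurotrophic (0.14), progenitor (0.0087), cell cycle (0.068), monoamine (0.046), chromatin (0.0030), cAMP (0.036), Wnt (0.087), Notch and Hedgehog (0.12), glutamate (0.15), GABAergic (0.10), synaptic (0.090), ribosomal (0.028), microglia (0.059), choroid plexus (0.11) and blood cell genes (0.16), while the median of all genes was 0.09. Of these lists, monoamine had passed, and its test direction stayed down. Fry turned neurotrophic (median -0.00018), glutamate (-0.0073), GABAergic (0.011) and synaptic genes (0.042). Quantile normalisation turned neurotrophic (0.032), cAMP (-0.013) and glutamate genes (0.021), and cyclic loess the same lists (0.056, -0.018 and 0.11). The median shift turned neurotrophic (0.033), chromatin (0.0062), glutamate (0.026) and mitochondrial genes (0.0068). The filter on all 8 arrays turned neurotrophic (0.095), Wnt (0.023), Notch and Hedgehog (0.021) and glutamate genes (0.062). Leaving out Y+I animals 2 and 3 turned neurotrophic (0.076), glutamate (0.012), GABAergic (0.0072) and microglia genes (0.0037). Leaving out 1 array turned neurotrophic (-0.021 to 0.084), synaptic (-0.014 to 0.11), astrocyte (-0.082 to 0.0042), glutamate (-0.022 to 0.15), mitochondrial (-0.075 to 0.029), chromatin (-0.10 to 0.0030), GABAergic (-0.016 to 0.061), ribosomal (-0.024 to 0.13) and cAMP genes (-0.021 to 0.038) and Arc (-0.25 to 0.038). The lower signal over background in Y+I limits what can be said of dim genes.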

Other observations

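The lists of mast cell markers and circadian clock genes were chosen only after the result was seen.

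Of 18 mast cell markers, 9 were measured, and the 2 that rose were Hdc and Tpsab1, the genes that prompted the list. Of the 9, 5 lay above 0, and their median log2 fold change was 1.46e-05 (limma camera adjusted p = 0.579 over both lists). Kit, the receptor for stem cell factor, was at -0.25 ± 0.15 (SE, adjusted p = 0.485), the granule proteoglycan gene Srgn at -0.24 ± 0.10 (adjusted p = 0.282), the prostaglandin synthase gene Hpgds at -0.47 ± 0.13 (adjusted p = 0.118) and the transcription factor gene Gata2 at -0.15 ± 0.21 (adjusted p = 0.79). The remaining members were not below 0. Mcpt4 was at 0.85 ± 0.79 (adjusted p = 0.6635), Mcpt8 at 0.06 ± 0.30 (adjusted p = 0.949) and Slc18a2 at 1.46e-05 ± 0.22.

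All 18 circadian clock genes were measured and 0 passed in limma, and 6 lay above 0. Their median log2 fold change was -0.10 (limma camera adjusted p = 0.579 over both lists). Per2 was at -0.48 ± 0.14 (SE, adjusted p = 0.137), Nr1d1 at -0.45 ± 0.16 (adjusted p = 0.203), Bhlhe41 at 0.57 ± 0.15 (adjusted p = 0.0935) and Dbp at -0.03 ± 0.12 (adjusted p = 0.946).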
